A study of Homo sapiens with 8 samples.

How the data were processed

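Gene expression was measured by RNA sequencing in 8 A549 libraries: 2 each from cells with a control shRNA, cells with an shRNA against AXL, control cells and cells given 40 nM TP-0903. Per the labels, cells grew in F12K medium with serum, total RNA was extracted with a column kit from biological replicates, and libraries were made with Nextera XT, for which no strand is stated. The treatment of the control cells, the duration of treatment and the sequence of the hairpins are not given in the sources used here. The authors aligned reads to GRCh38 with STAR (version 2.5.3a) and quantified genes with RSEM, whose version and annotation are not given in the sources used here.

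The deposited expected counts are RSEM's estimated reads per gene and library and were not normalized by the authors. The deposited TPM values were scaled by the authors' RSEM run for transcript length and depth within each library. The deposited FPKM values come from the same run per the file headers and were not used in any test. The deposited effective lengths served as offsets in an alternative. Each library had its own file of 58302 genes, of which 58039 had the same Ensembl ID in GENCODE release 29, the source of positions, and the 263 others have no position here. Library totals ran from 30067011 to 44217023 expected counts. Between both libraries of a group, 50.7% to 56.9% of genes differed by more than counting error at the 5% level.

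Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the groups, and libraries were scaled by trimmed mean of M values (TMM). All 8 libraries entered a single edgeR (4.0.16) quasi-likelihood fit with 1 term per group, which shares the spread over the groups (prior degrees of freedom 3.33). The 3 main contrasts were AXL shRNA minus control shRNA, TP-0903 minus control, and the difference of these effects (an interaction test), all two-sided. Control shRNA minus control was added as a description. Values of p were adjusted by the Benjamini-Hochberg method over all tested genes of a contrast, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are counts per library total scaled by TMM, and principal components used log2 CPM with a pseudocount of 2. The first components took 40.7%, 23.1%, 14.2% and 11.6% of the variance.

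A set of 46 gene lists was written from general knowledge before the data were examined, and 44 with 5 or more tested members were tested with camera in limma (3.58.1) on voom values, with an inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Counts of members that passed over all genes are followed by counts with p adjusted over the list alone. A call lost without a library is given with the adjusted p of the fit without it.

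Genes named in the text were chosen by a rule fixed in advance. AXL, TYRO3, MERTK, GAS6, PROS1, JAK1, JAK2, STAT3, SMAD2 and SMAD4 were always named. So were the 8 protein-coding genes with the largest rise and the 8 with the largest fall past the threshold, with a mean of at least 5 CPM and both treated libraries on the same side of both controls. For each list that passed, or that had 3 or more members past the threshold, up to 4 members with the smallest p in the direction of the test were taken, and the text prints the first of these. Some items chosen by the rule, and a gene list, are not reported here. For the difference of effects the 5 genes with the smallest p in each direction were named. CDH5 and the genes named for the P number were named after their values were seen, and BTG2, PHGDH and SLC6A9 were taken from the named genes as examples of shared change.

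The meaning of the number after P is not stated, and it was checked whether it pairs libraries. Deviations from the group means correlated, across genes, at 0.444 between control shRNA and AXL shRNA libraries of the same number and at 0.450 between control and TP-0903 libraries of the same number, against 0.171 to 0.309 for pairs of groups that share no number, matched by low and high number. The numbers were therefore taken to pair the libraries, and the fit with the number as a block is given beside a result where it changes the call or moves a count by over 1.5 times.

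Alternatives covered the scaling, the filter, DESeq2 (1.42.0), limma-voom, limma on log2 TPM with a pseudocount of 1, effective lengths, the block, the P number in 2 levels, the 4 libraries of a comparison alone, a test against a fold change of 1.5, and each library left out in turn. Others were added after the data were seen: exchanged controls, and counts without cell cycle and repair genes or without genes that hold a 3' UTR site. The 3' UTR sites were found by a search made after the data were seen. It took 10622 protein-coding genes with a mean of at least 5 CPM and a 3' UTR of at least 50 bases in 1 GENCODE transcript per gene, and regressed the log2 fold change, held within -3 and 3, on the presence of each of 15523 7-base sequences, with 3' UTR length and GC content as covariates. Genes without a searched 3' UTR (229) were left out. The search was repeated on odd-numbered autosomes (5697 genes) and on all other chromosomes (4925 genes).

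The pipeline was tested on simulated data of the same depth and spread, with 200 changed genes in each of 3 draws. Genes changed by 4-fold were recovered in 79.8% of cases for AXL shRNA, 84.3% for TP-0903 and 55.6% for the difference, and those changed by 2-fold in 25.9%, 32.8% and 3.98%. Of the calls, 7.43%, 6.85% and 10.6% were false. A planted list was found and 0 of 20 drawn lists passed in camera. In the 3' UTR search, 10 of 10 planted sequences ranked first. The work used R 4.3.3, the data.table package (1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.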

Results

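A549 is an established human lung adenocarcinoma cell line with mutant KEAP1. The series set out to look for routes of resistance to TP-0903, a small-molecule inhibitor of the receptor tyrosine kinase AXL. RNA sequencing libraries came from 8 cultures in 4 groups of 2: cells carrying a control short hairpin RNA (shRNA), cells carrying an shRNA against AXL, control cells, and cells given 40 nM TP-0903. Each label also carries a number after the letter P, whose meaning is not given in the sources used here. P15 and P3 each marked a control shRNA and an AXL shRNA library, and P17 and P4 each marked a control and a TP-0903 library. The total of expected counts was 30067011 (P15) and 31925904 (P3) for control shRNA, 36028048 (P15) and 44217023 (P3) for AXL shRNA, 36258608 (P17) and 38908570 (P4) for control, and 33013203 (P17) and 34522110 (P4) for TP-0903. A total of 17676 genes passed the count filter. Across genes, which are not independent replicates, log2 CPM (counts scaled to the library total) correlated at 0.979 to 0.983 between the libraries of a group and at 0.927 to 0.976 between libraries of different groups. The biological coefficient of variation was 21.5%. Group values are mean CPM ± SD with n = 2 libraries, and changes are log2 fold changes.

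AXL, the target of both the hairpin and the drug, was lower with its shRNA in both cultures, and its transcript was not lower with the inhibitor in either. The gene (ENSG00000167601) lies on the plus strand of chromosome 19, at 41219203 to 41261766 in GRCh38. It stood at 85.1 CPM (P15) and 139 CPM (P3) with control shRNA and at 55.4 (P15) and 63.0 CPM (P3) with AXL shRNA, which left 65.1% and 45.1% of the level in the control library of the same P number. Control cultures held 216 (P17) and 105 CPM (P4), and TP-0903 cultures held 280 and 153 CPM, or 129% and 147% of the control library of the same P number. The log2 fold change with AXL shRNA was -0.92 (SE 0.42, adjusted p = 0.12), and with the replicate block it was -0.89 (adjusted p = 8.58e-04). With TP-0903 it was 0.43 (SE 0.41, adjusted p = 0.544), and 0.46 (adjusted p = 0.0354) with the block. Over all alternatives the adjusted p ran from 4.45e-08 to 0.445 for the shRNA and from 0.00798 to 1 for the drug. Without TP-0903 P17, in a fit that ignores the pairs, the drug value was -0.064.

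**Figure D1:**
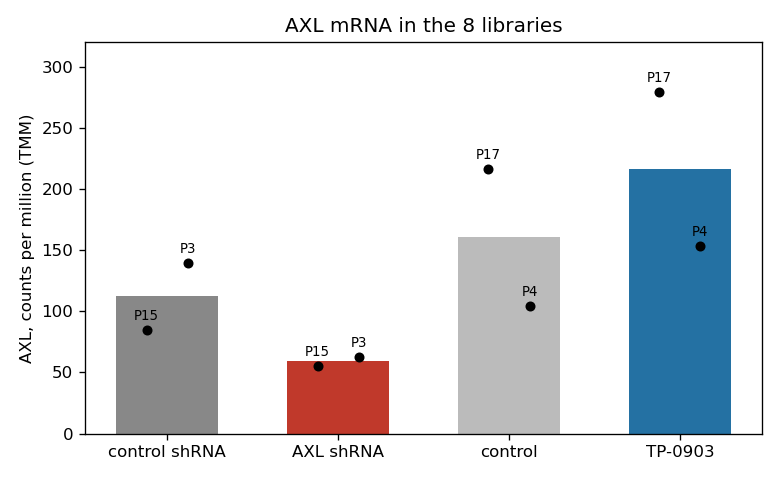
AXL in each of the 8 libraries in CPM (vertical axis, from 0), with a bar at the mean of each group of 2 and 1 point per library, marked with its P number. Both AXL shRNA libraries (55.4 and 63.0 CPM) lie below both control shRNA libraries (85.1 and 139 CPM), and each TP-0903 library lies above the control library of its P number.

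The first comparison, AXL shRNA against control shRNA, asked what changes when AXL is lowered. Of the listed genes, 24 of 42 interferon-stimulated, 21 of 26 NF-kB, 21 of 27 cholesterol synthesis, 8 of 14 fatty acid synthesis, 24 of 33 glycolysis and 15 of 19 heat shock genes rose, and 26 of 37 targets of ATF4, the transcription factor of the integrated stress response, fell. These lists passed in the camera test, which took a preset correlation between genes, and no list passed when that correlation was estimated (smallest adjusted p = 0.211 with an estimated correlation). STAT3 (ENSG00000168610), a transcription factor downstream of cytokine receptors, rose from 274 ± 46.6 to 687 ± 57.1 CPM (log2 fold change 1.33, SE 0.16, adjusted p = 0.00118). SMAD2 (ENSG00000175387), which carries signals from TGF-beta family receptors to the nucleus, fell from 198 ± 20.9 to 68.3 ± 18.2 CPM (-1.54, SE 0.18, adjusted p = 0.00121). Its partner SMAD4 (ENSG00000141646) fell from 58.7 ± 0.398 to 30.1 ± 2.13 CPM (-0.96, SE 0.10, adjusted p = 8.65e-04). The 3' UTR of SMAD4 holds the 8-base sequence TGAAGGAA and that of SMAD2 holds both of its 7-base parts apart. Genes with the 8-base sequence in the 3' UTR differed from genes with no such site by a shift of -0.51. A gene said here to hold a site carries the 8-base sequence or a 7-base part of it.

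Of 17676 genes, 6627 changed in edgeR's quasi-likelihood test, 3275 higher and 3352 lower, and 3313 of them changed by more than 2-fold. Limma on log2 TPM gave 2008 higher and 4404 lower (31.3% higher against 49.4%) and shifted the median gene by -0.21. Effective lengths as offsets gave 49.7%. Without the control shRNA P15 library the count was 4408. Of the named genes that passed, 148 of 169 kept the call whichever library was left out.

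Type I interferon-stimulated genes act in antiviral defence, and 24 of 42 members rose (26 adjusted over the list alone). In the camera test this list had median 1.53, adjusted p = 5.34e-08, and adjusted p = 0.595 with an estimated correlation. OAS3, an enzyme that senses double-stranded RNA and holds a site, rose from 36.3 ± 0.61 to 193 ± 24.3 CPM. SAMD9, an antiviral factor, rose by 1.90 (SE 0.16), DDX58, the RNA sensor RIG-I, rose by 2.07 (SE 0.20), and ISG15, a ubiquitin-like modifier, rose by 3.39 (SE 0.36). NF-kB and inflammatory cytokine genes did likewise: 21 of 26 members rose and 1 fell (21 and 1 adjusted over the list alone; median 2.43, adjusted p = 1.76e-07, and adjusted p = 0.595 with an estimated correlation). SOD2, the mitochondrial superoxide dismutase, rose from 99.1 ± 9.45 to 1143 ± 364 CPM although it holds a site. BIRC3, an inhibitor of apoptosis, rose by 3.30 (SE 0.30), and the chemokine CXCL8 rose by 3.16 (SE 0.33). The leukocyte gene PTPRC lay at or under 0.0302 CPM in the AXL shRNA libraries. Of the 4 blood cell markers with enough counts to test, 2 rose and 1 fell: CD79A from 0.274 ± 0.0911 to 2.18 ± 1.23 CPM, HBA1 from 0 to 0.693 ± 0.0833 CPM and CD14 from 6.73 ± 0.88 to 2.79 ± 0.445 CPM (-1.27, SE 0.37). The other, CD68, stood at 16.6 ± 5.98 CPM with control shRNA and 13.5 ± 1.32 CPM with AXL shRNA (-0.30, SE 0.31, adjusted p = 0.471). Among the secretory and senescence-associated genes, 12 of 22 members rose and 1 fell (12 and 1 adjusted over the list alone; median 1.25, adjusted p = 0.00571, and adjusted p = 0.595 with an estimated correlation). They included IGFBP6, an IGF-binding protein with a site, which rose by 1.75 (SE 0.14), and the monocyte chemokine CCL2, which rose by 4.40 (SE 0.53). In the MHC class I list, 4 of 19 members rose and 1 fell (4 and 1 adjusted over the list alone; median 0.59, adjusted p = 0.0343, and adjusted p = 0.741 with an estimated correlation). The peptide transporter TAP1 rose by 1.53 (SE 0.24) and the class I molecule HLA-E rose by 0.75 (SE 0.16). Of the immediate early genes, 7 of 17 members rose (8 adjusted over the list alone; median 0.84, adjusted p = 0.0141, and adjusted p = 0.595 with an estimated correlation). The antiproliferative gene BTG2 rose by 2.33 (SE 0.15) and IER5, which holds a site, rose by 0.90 (SE 0.15). On TPM, where the median gene lies 0.21 lower, the medians were 0.83 for the interferon list, 1.65 for the NF-kB list, 0.53 for the secreted factors, 0.24 for the MHC class I list and 0.46 for the immediate early genes. Without control shRNA P15, adjusted p was 0.113 for CD14. Without AXL shRNA P15, adjusted p was 0.126 for CD14 and 0.195 for the MHC class I list. Without control shRNA P3, adjusted p was 0.0656 for CD14 and 0.171 for the MHC class I list. Without AXL shRNA P3, adjusted p was 0.0768 for CD14.

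Genes of lipid synthesis and glycolysis were among those that rose. In cholesterol synthesis, 21 of 27 members rose and 2 fell (21 and 3 adjusted over the list alone; median 1.09, adjusted p = 1.89e-06, and adjusted p = 0.595 with an estimated correlation). FDFT1, which makes squalene, rose from 76.9 ± 5.68 to 195 ± 9.15 CPM, and DHCR7, which makes cholesterol from its last precursor, rose by 1.34 (SE 0.12). In fatty acid synthesis, 8 of 14 members rose and 1 fell (9 and 1 adjusted over the list alone; median 0.77, adjusted p = 0.00281, and adjusted p = 0.595 with an estimated correlation). FASN, the fatty acid synthase, rose from 180.4 ± 4.45 to 834 ± 56.9 CPM, and the elongase ELOVL6, which holds a site, rose by 1.19 (SE 0.13). Against the control mean, the median of the cholesterol list lay at -0.90 (P15) and -0.97 (P3) in the control shRNA libraries, and in the AXL shRNA libraries it lay at 0.18 and 0.23. For the fatty acid list these values were -0.53 and -0.70 with control shRNA and 0.11 and 0.07 with AXL shRNA. AXL shRNA minus control gave medians of 3.6e-04 for the cholesterol list (9 of 27 members higher and 5 lower) and 0.05 for the fatty acid list (3 of 14 higher and 1 lower), so both rises are measured from a low control shRNA level. In hypoxia and glycolysis, 24 of 33 members rose and 1 fell (24 and 1 adjusted over the list alone; median 0.88, adjusted p = 6.02e-06, and adjusted p = 0.211 with an estimated correlation). The glycolytic enzymes ALDOA, PGAM1 and HK2 rose by 1.19 (SE 0.11), 1.23 (SE 0.12) and 2.57 (SE 0.27). The medians on TPM were 0.81 for the cholesterol list, 0.50 for the fatty acid list and 0.59 for the glycolysis list.

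Stress programmes moved in opposite directions. Of the heat shock genes, mostly chaperones, 15 of 19 members rose and 1 fell (16 and 1 adjusted over the list alone; median 1.12, adjusted p = 5.32e-06, and adjusted p = 0.595 with an estimated correlation). The median of this list lay at -0.69 and -0.52 in the control shRNA libraries against the control mean, and AXL shRNA minus control gave 0.63 (10 of 19 members higher and 1 lower). The collagen chaperone SERPINH1 rose by 2.01 (SE 0.17) and the small heat shock protein HSPB1 rose by 2.73 (SE 0.23). In the integrated stress response list, 1 of 37 members rose and 26 fell (1 and 31 adjusted over the list alone; median -1.27, adjusted p = 1.10e-08, and adjusted p = 0.595 with an estimated correlation). The glycine transporter SLC6A9 fell by 1.79 (SE 0.13), and the transfer RNA synthetase genes GARS, which holds a site, and EPRS fell by 2.34 (SE 0.20) and 1.06 (SE 0.10). This list lay higher in control shRNA than in control (median 0.65), and AXL shRNA minus control gave a median of -0.66 (4 of 37 members higher and 19 lower), while AXL shRNA minus TP-0903 gave -0.045 (5 higher and 6 lower). Among endoplasmic reticulum chaperones and unfolded protein response genes, 1 of 25 members rose and 11 fell (1 and 12 adjusted over the list alone; median -0.40, adjusted p = 0.00152, and adjusted p = 0.35 with an estimated correlation). SEL1L and DNAJC3, which act in protein quality control, and the transcription factor XBP1 fell by 2.35 (SE 0.13), 1.38 (SE 0.15) and 2.69 (SE 0.32), and each of these genes holds a site. Of the mitochondrially encoded genes, 9 of 15 members rose (9 adjusted over the list alone; median 0.77, adjusted p = 1.12e-04, and adjusted p = 0.66 with an estimated correlation). The ribosomal RNA genes MT-RNR1 and MT-RNR2 rose by 1.90 (SE 0.19) and 1.68 (SE 0.18). Mitochondrial transcripts took 6.79% (P15) and 7.79% (P3) of counts with AXL shRNA and 3.94% and 5.17% with control shRNA. On TPM the list medians were 0.91 for the heat shock genes, -1.45 for the integrated stress response, -0.54 for the chaperones and 0.54 for the mitochondrially encoded genes.

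Some replication genes were also higher with AXL shRNA: in the G1/S list, 19 of 41 members rose and 3 fell (21 and 3 adjusted over the list alone; median 0.53, adjusted p = 0.00213, and adjusted p = 0.74 with an estimated correlation). ORC6 and MCM5, which load and form the replicative helicase, rose by 2.16 (SE 0.21) and 1.28 (SE 0.13). In the G2/M list, 12 of 40 members rose and 1 fell (12 and 1 adjusted over the list alone; median 0.35, adjusted p = 0.0166, and adjusted p = 0.758 with an estimated correlation). The mitotic kinase AURKA rose by 1.41 (SE 0.16) and cyclin B1, CCNB1, rose by 1.13 (SE 0.20). All 4 shRNA libraries lay far below the control libraries in this list, at -3.21 and -2.99 with control shRNA and -2.86 and -2.61 with AXL shRNA. In the list of MYC targets and ribosome biogenesis genes, 10 of 33 members rose and 2 fell (10 and 2 adjusted over the list alone; median 0.29, adjusted p = 0.0161, and adjusted p = 0.758 with an estimated correlation). Against control, AXL shRNA gave a median of 0.047 for this list (3 of 33 members higher and 7 lower). The spermidine synthase SRM rose by 1.17 (SE 0.12) and MYC itself rose by 1.23 (SE 0.20). Of the mesenchymal genes, 12 of 27 members rose and 2 fell (12 and 2 adjusted over the list alone; median 1.21, adjusted p = 7.91e-04, and adjusted p = 0.595 with an estimated correlation). SPARC, a matrix glycoprotein, rose from 7.55 ± 2.63 to 167 ± 55.9 CPM, and the collagen COL3A1 rose by 4.29 (SE 0.51). Fibroblast markers overlapped this list, and 3 of 6 members rose (3 adjusted over the list alone; adjusted p = 0.093, and 0.0185 with the replicate block). Of the epithelial junction and keratin genes, 10 of 24 members rose and 3 fell (10 and 4 adjusted over the list alone; median 0.72, adjusted p = 0.0326, and adjusted p = 0.676 with an estimated correlation). The claudin CLDN4 rose by 2.48 (SE 0.22) and the keratin KRT8 rose by 1.94 (SE 0.23). Of the stem cell markers, 8 of 17 members rose (8 adjusted over the list alone; median 0.49, adjusted p = 0.0133, and adjusted p = 0.595 with an estimated correlation). The integrin ITGA6 rose by 1.71 (SE 0.14) and the aldehyde dehydrogenase ALDH1A3, which holds a site, rose by 2.38 (SE 0.27). Medians on TPM were 0.12 for the G1/S list, 0.08 for the G2/M list, 0.09 for the MYC targets, 0.81 for the mesenchymal genes, 0.37 for the keratin list and 0.57 for the stem cell markers. With control shRNA P15 left out, adjusted p was 0.0698 for the G2/M list and 0.386 for the MYC target list. With AXL shRNA P3 left out, adjusted p was 0.0923 for the G2/M list. With AXL shRNA P15 left out, adjusted p was 0.195 for the keratin list and 0.0751 for the stem cell list. With control shRNA P3 left out, adjusted p was 0.121 for the keratin list.

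STAT3 and JAK1 rose with AXL shRNA, and JAK2, SMAD2 and SMAD4 fell. No member of AXL's receptor family or its ligands passed the test without the replicate block. Among these TAM receptors and ligands, AXL included, 0 of 5 passed the edgeR test, with 0 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.588). The receptors TYRO3 and MERTK stood at -0.29 (SE 0.22, adjusted p = 0.341) and 0.88 (SE 0.78, adjusted p = 0.406, and 0.00668 with the replicate block). The ligands GAS6 and PROS1 stood at 0.07 (SE 0.27, adjusted p = 0.857) and -1.12 (SE 0.50, adjusted p = 0.115, and 9.77e-05 with the block). Without control shRNA P3 the TYRO3 value turned to 0.032, and the GAS6 value turned to -0.11 on TPM and to -0.029 without control shRNA P15. The cytokine receptor kinase JAK1 rose from 246 ± 15 to 369 ± 44.1 CPM (0.58, SE 0.14, adjusted p = 0.0138). Its relative JAK2 fell from 13.5 ± 1.22 to 9.09 ± 1.32 CPM (-0.57, SE 0.17, adjusted p = 0.0337), a call that held without AXL shRNA P15 and was lost without any other single library (adjusted p = 0.0542 to 0.157). In the JAK-STAT list, 8 of 25 members rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.173), and the receptor IL6R, which holds a site, rose by 2.84 (SE 0.15). Of the SMAD family and TGF-beta receptors, 3 of 17 members rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.992, median 0.06, mean -0.07). Of the TGF-beta targets, 7 of 25 members rose and 4 fell (7 and 4 adjusted over the list alone; adjusted p = 0.273), and SKIL and PMEPA1, feedback inhibitors that hold sites, fell by 0.86 (SE 0.13) and 1.77 (SE 0.29). Of other receptor tyrosine kinases and ligands, 7 of 32 members rose and 7 fell (7 and 7 adjusted over the list alone; adjusted p = 0.978, median 0.06, mean -0.06). The growth factor VEGFA, which holds a site, fell by 1.64 (SE 0.19), and the receptor FGFR1 rose by 1.18 (SE 0.15). Without control shRNA P15, adjusted p was 0.0757 for JAK1. Without AXL shRNA P3, adjusted p was 0.0811 for JAK1.

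Among the largest rises were UBD (ENSG00000213886), a ubiquitin-like protein induced by cytokines, from 0.108 ± 0.152 to 46.9 ± 3.27 CPM, SCG3, a secretory granule protein, from 0.0603 ± 0.0417 to 25.4 ± 3.78 CPM, and the olfactory receptor gene OR2I1P, which holds a site, from 0.0769 ± 0.109 to 22.8 ± 4.01 CPM. The keratin KRT6A went from 0.261 ± 0.284 to 65.7 ± 38.5 CPM, and the oxidised lipoprotein receptor OLR1 from 0.168 ± 0.11 to 20.1 ± 4.39 CPM. RUNDC3A went from 0.377 ± 0.229 to 36.7 ± 2.12 CPM, the adaptor subunit AP3B2 from 0.561 ± 0.0107 to 34.4 ± 1.45 CPM and the interleukin receptor IL7R from 0.275 ± 0.22 to 16.8 ± 6.49 CPM. UBD and OR2I1P overlap on opposite strands, and both overlap GABBR1 (mean 11.7 CPM), which shares the strand of UBD, so their counts are uncertain. OLR1, RUNDC3A and AP3B2 overlap TMEM52B, RUNDC3A-AS1 and CPEB1-AS1 on the other strand, which had means of 0.255, 1.38 and 0.204 CPM. The largest falls were in ADM2, a peptide hormone gene (-5.32, SE 0.78), the calcium channel CACNA1D (-4.91, SE 0.77), the mucin MUC5B (-4.40, SE 1.31), FAM129A (-4.26, SE 0.56) and the matrix protein SMOC1 (-3.76, SE 0.47). Next came PHGDH, the first enzyme of serine synthesis (-3.74, SE 0.39), SMIM14 (-3.51, SE 0.26) and the neurotrophin receptor NTRK3 (-3.50, SE 0.32). MUC5B fell from 354 ± 218 to 16.9 ± 22.8 CPM (adjusted p = 0.0346). This call was lost without any single library other than the AXL shRNA ones, with adjusted p = 0.112 without control shRNA P15, 0.0529 without control shRNA P3, 0.0535 without control P17, 0.050027 without TP-0903 P17, 0.0533 without control P4 and 0.0511 without TP-0903 P4. FAM129A, SMOC1, SMIM14 and NTRK3 hold a site, and CACNA1D, SMOC1 and SMIM14 overlap CHDH and DCP1A (18.6 and 26.8 CPM), RPL7AP6 (18.4 CPM) and UGDH-AS1 (1.29 CPM) on the other strand, which makes those counts uncertain.

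In all, 18 of 44 lists passed, 16 higher and 2 lower. With an estimated correlation between genes camera passed 0 (2 at an unadjusted p under 0.05), and fry, which asks whether a list moves one way, passed 22. The other lists with 3 or more changed members had no passing direction in camera. In the oxidative phosphorylation list, 13 of 45 members rose and 3 fell (13 and 2 adjusted over the list alone; adjusted p = 0.0773). In the cytosolic ribosomal protein list, 6 of 75 members rose and 15 fell (6 and 12 adjusted over the list alone; adjusted p = 0.546), and in the lysosome list, 12 of 36 members rose and 9 fell (12 and 10 adjusted over the list alone; adjusted p = 0.984). In the NRF2 target list, 6 of 32 members rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.595), with median -0.07 and mean 0.10. The BCL2 family list had median -0.03 and mean 0.43, 6 of 16 members rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.468), and BIK, a promoter of cell death, rose by 4.44 (SE 0.30). In the list of liver and gut genes that A549 cells express, 1 of 18 members rose and 1 fell (0 and 0 adjusted over the list alone; adjusted p = 0.83, median 0.13, mean -0.27).

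**Figure D2:**
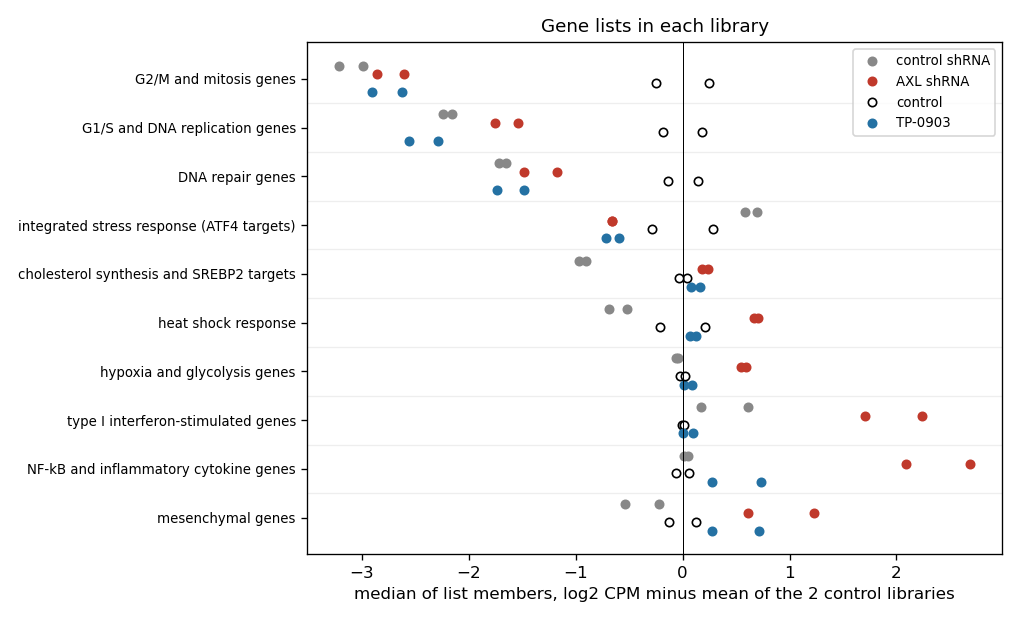
Median over the members of 10 gene lists in each of the 8 libraries, as log2 CPM minus the mean of both control libraries (horizontal axis), with 1 row per list and 1 point per library. The interferon list lies at 2.24 and 1.71 in the AXL shRNA libraries, and the G2/M list lies between -3.21 and -2.61 in the 6 libraries other than control.

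The second comparison, TP-0903 against control, asked what changes in cells given the inhibitor. Of the listed genes, 39 of 41 in DNA replication, 39 of 40 in mitosis and 24 of 30 in DNA repair fell. These lists passed in camera, and no list passed when the correlation between genes was estimated (smallest adjusted p = 0.338 with an estimated correlation). MCM10 (ENSG00000065328), which is needed to start replication, fell from 61.6 ± 16.7 to 3.42 ± 0.445 CPM (-4.17, SE 0.27, adjusted p = 4.70e-04), and RRM2, a subunit of ribonucleotide reductase, fell from 192 ± 21.8 to 15 ± 1.08 CPM (-3.68, SE 0.20). MYL9 (ENSG00000101335), a regulatory light chain of myosin, rose from 12.6 ± 0.78 to 123 ± 17.4 CPM (3.28, SE 0.25, adjusted p = 6.50e-04). The control libraries stood apart from all 6 others in the cell cycle genes, with the G2/M median of both control shRNA libraries at -3.21 and -2.99 against -2.62 and -2.91 in the TP-0903 libraries.

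In edgeR's test 1989 of 17676 genes changed, 866 higher and 1123 lower, and 982 of them by more than 2-fold. With the replicate block the count was 4647, 2285 higher and 2362 lower. It was 584 without control P17, 489 without TP-0903 P17, 898 without control P4 and 1089 without TP-0903 P4, and 37 of 107 named genes kept the call whichever library was left out. With control shRNA in place of control it was 3320, and 934 of the 1989 genes (47.0%) were then called in the same direction.

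In the G1/S list, 39 of 41 members fell (40 adjusted over the list alone; median -2.48, adjusted p = 4.45e-40, and adjusted p = 0.338 with an estimated correlation). MCM5, a subunit of the replicative helicase, fell by 2.84 (SE 0.14), the primase PRIM1 fell by 3.51 (SE 0.18) and CDC45, another part of the helicase, fell by 3.70 (SE 0.19). In the G2/M list, 39 of 40 members fell (40 adjusted over the list alone; median -2.77, adjusted p = 2.45e-39, and adjusted p = 0.338 with an estimated correlation). HMMR, a spindle protein, fell by 2.98 (SE 0.17), the kinase CDK1 fell by 2.97 (SE 0.18) and the mitotic motor KIF11 fell by 3.03 (SE 0.19). In the DNA repair list, 24 of 30 members fell (28 adjusted over the list alone; median -1.59, adjusted p = 7.17e-23, and adjusted p = 0.338 with an estimated correlation). FANCI, of the crosslink repair pathway, fell by 2.65 (SE 0.15) and the exonuclease EXO1 fell by 3.41 (SE 0.19). These 3 lists were also lower than control in the control shRNA cultures, which had no drug, with medians of -2.23, -3.14 and -1.70. The largest falls were all in genes of the cell cycle: the transcription factors E2F2 (-4.40, SE 0.37), E2F8 (-3.80, SE 0.32) and MYBL2 (-3.56, SE 0.26), the licensing factor CDT1 (-3.82, SE 0.33) and its ubiquitin ligase partner DTL (-3.77, SE 0.29), with MCM10, CDC45 and RRM2. RRM2 overlaps AC007240.1 (0.747 CPM). Leaving out the members of these lists gave 1887 changed genes. Of the replication-dependent histone genes, 5 of 11 members rose (7 adjusted over the list alone; median 0.85, adjusted p = 3.80e-04, and adjusted p = 0.537 with an estimated correlation). HIST1H2BC rose by 2.47 (SE 0.27) and HIST1H4H rose by 2.0 (SE 0.27).

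Genes of protein synthesis were among those that fell with TP-0903. Of the cytosolic ribosomal protein genes, 20 of 75 members fell (42 adjusted over the list alone; median -0.42, adjusted p = 4.41e-17, and adjusted p = 0.624 with an estimated correlation). RPS29 fell by 0.63 (SE 0.10) and RPS3 fell by 0.79 (SE 0.13). Of the MYC targets and ribosome biogenesis genes, 6 of 33 members fell (6 adjusted over the list alone; median -0.33, adjusted p = 3.52e-04, and adjusted p = 0.751 with an estimated correlation). The nucleolar methyltransferase FBL fell by 1.0 (SE 0.15) and NOP56 fell by 0.82 (SE 0.13). In control shRNA against control the medians of these lists were 0.15 and -0.34. In the integrated stress response list, 11 of 37 members fell (1 and 22 adjusted over the list alone; median -0.72, adjusted p = 7.02e-06, and adjusted p = 0.624 with an estimated correlation). SLC6A9 fell by 1.38 (SE 0.13), PHGDH fell by 2.85 (SE 0.37) and the transfer RNA synthetase gene AARS fell by 1.39 (SE 0.20). This list lay higher in control shRNA than in control (median 0.65) and lower in AXL shRNA than in control (-0.66). Of the mitochondrially encoded genes, 2 of 15 members rose (15 adjusted over the list alone; median 0.66, adjusted p = 2.72e-07, and adjusted p = 0.568 with an estimated correlation). MT-CO2 rose by 0.67 (SE 0.15) and MT-CYB rose by 0.69 (SE 0.17). Mitochondrial transcripts took 5.16% (P17) and 5.82% (P4) of counts with TP-0903 and 3.68% and 3.58% in control. Without control P17, adjusted p was 0.0542 for RPS29, 0.0698 for RPS3, 0.0551 for FBL, 0.0715 for NOP56, 0.101 for MT-CO2 and 0.119 for MT-CYB. Without TP-0903 P17, adjusted p was 0.0597 for RPS29, 0.0989 for RPS3, 0.0695 for FBL, 0.0835 for NOP56, 0.0597 for AARS, 0.143 for MT-CO2 and 0.206 for MT-CYB. Without control P4, adjusted p was 0.0682 for RPS29, 0.0569 for RPS3, 0.135 for MT-CO2 and 0.191 for MT-CYB. Without TP-0903 P4, adjusted p was 0.0721 for RPS29, 0.0522 for NOP56, 0.0848 for MT-CO2 and 0.108 for MT-CYB. Without AXL shRNA P15, adjusted p was 0.0586 for MT-CYB. Without AXL shRNA P3, adjusted p was 0.0609 for MT-CYB.

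Other lists that passed were mostly higher. Control shRNA minus control gave the lists below medians of 0.17, 0.21, 0.37, 0.24, 0.03, -0.42, 0.31 and 0.14, in order. Of the lysosome and autophagy genes, 10 of 36 members rose (14 adjusted over the list alone; median 0.37, adjusted p = 1.69e-05, and adjusted p = 0.537 with an estimated correlation). The sialidase NEU1 rose by 0.82 (SE 0.14) and the proton pump subunit ATP6V1H rose by 0.72 (SE 0.13). Of the YAP and TAZ targets, 4 of 21 members rose (12 adjusted over the list alone; median 0.59, adjusted p = 5.94e-05, and adjusted p = 0.382 with an estimated correlation). The membrane repair protein MYOF rose by 1.08 (SE 0.13) and the growth arrest gene GADD45A rose by 1.73 (SE 0.26). Of the drug efflux transporters, 3 of 12 members rose (4 adjusted over the list alone; median 0.40, adjusted p = 0.00973, and adjusted p = 0.537 with an estimated correlation). ABCC5 rose by 0.72 (SE 0.09) and the vault protein MVP by 0.67 (SE 0.13). In the secretory and senescence-associated list, 5 of 22 members rose and 1 fell (6 and 1 adjusted over the list alone; median 0.42, adjusted p = 0.0169, and adjusted p = 0.624 with an estimated correlation). The protease inhibitor TIMP2 rose by 1.01 (SE 0.17) and the cell cycle inhibitor CDKN1A rose by 1.5 (SE 0.25). Of the NF-kB genes, 4 of 26 members rose and 1 fell (9 and 1 adjusted over the list alone; median 0.52, adjusted p = 0.0226, and adjusted p = 0.751 with an estimated correlation). TNFAIP2 rose by 1.04 (SE 0.16) and SOD2 by 1.20 (SE 0.26). Of the mesenchymal genes, 4 of 27 members rose (4 adjusted over the list alone; median 0.22, adjusted p = 0.0405, and adjusted p = 0.751 with an estimated correlation). The tropomyosin TPM2 rose by 1.53 (SE 0.21) and the collagen COL6A1 rose by 1.28 (SE 0.31). In the MHC class I list, 1 of 19 members rose (1 adjusted over the list alone; median 0.46, adjusted p = 0.00414, and adjusted p = 0.729 with an estimated correlation). TAP1 rose by 1.57 (SE 0.24). Of the chaperones, 0 passed edgeR's test (5 higher and 1 lower at an unadjusted p under 0.05). The list passed in camera (median 0.17, adjusted p = 0.0386, and adjusted p = 0.382 with an estimated correlation). With the block it did not (adjusted p = 0.0548). With control P17 left out, adjusted p was 0.0838 for NEU1, 0.084 for ATP6V1H, 0.0685 for GADD45A, 0.114 for MVP, 0.065 for CDKN1A, 0.0522 for the NF-kB list, 0.0652 for TNFAIP2, 0.1 for SOD2, 0.111 for COL6A1, 0.0552 for TAP1 and 0.0712 for the chaperone list. With TP-0903 P17 left out, adjusted p was 0.101 for NEU1, 0.0756 for ATP6V1H, 0.0535 for GADD45A, 0.126 for MVP, 0.1 for the secretory list, 0.0833 for TIMP2, 0.073 for CDKN1A, 0.213 for the NF-kB list, 0.0581 for TNFAIP2, 0.17 for SOD2, 0.0985 for the mesenchymal list, 0.232 for COL6A1, 0.0985 for the MHC class I list and 0.0715 for the chaperone list. With control P4 left out, adjusted p was 0.0593 for ATP6V1H, 0.0873 for MVP, 0.0578 for TIMP2, 0.0522 for TNFAIP2, 0.137 for SOD2, 0.136 for the mesenchymal list, 0.19 for COL6A1 and 0.0559 for TAP1. With TP-0903 P4 left out, adjusted p was 0.0606 for ATP6V1H, 0.0544 for the efflux list, 0.0696 for MVP and 0.0625 for the chaperone list. With control shRNA P15 left out, adjusted p was 0.0544 for COL6A1. With control shRNA P3 left out, adjusted p was 0.0576 for COL6A1.

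In the JAK-STAT list, 3 of 25 members rose (3 adjusted over the list alone; median 0.15, adjusted p = 0.0155, and adjusted p = 0.338 with an estimated correlation). STAT3 rose from 301 ± 24.8 to 588 ± 45.3 CPM (0.96, SE 0.16, adjusted p = 0.01). JAK1 rose from 307 ± 14.7 to 505 ± 50.7 CPM (0.72, SE 0.14, adjusted p = 0.017), and the oncostatin M receptor OSMR rose by 0.62 (SE 0.13). JAK2 stood at 0.07 (SE 0.17, adjusted p = 0.837), SMAD4 at -0.27 (SE 0.10, adjusted p = 0.137) and SMAD2 at -0.43 (SE 0.18, adjusted p = 0.166, and 0.0217 with the replicate block). In the TAM list 0 members passed in edgeR, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.909, median -0.04, mean 0.06). TYRO3 stood at -0.68 (SE 0.22, adjusted p = 0.0917, and 0.0179 with the block) and GAS6 at 0.67 (SE 0.27, adjusted p = 0.155, and 0.0282 with the block). MERTK and PROS1 stood at -0.04 (SE 0.79, adjusted p = 0.983) and -0.08 (SE 0.49, adjusted p = 0.942), and their direction turned without TP-0903 P17 (0.53 and 0.48) and without control P4 (0.81 and 0.65). MERTK turned also on TPM (0.10) and with effective lengths as offsets (0.23). Without control P17, adjusted p was 0.0522 for the JAK-STAT list, 0.0514 for STAT3, 0.111 for JAK1 and 0.133 for OSMR. Without TP-0903 P17, adjusted p was 0.0777 for STAT3, 0.0598 for JAK1 and 0.164 for OSMR. Without control P4, adjusted p was 0.0613 for STAT3, 0.0677 for JAK1 and 0.0581 for OSMR. Without TP-0903 P4, adjusted p was 0.0798 for JAK1.

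Among the largest rises besides MYL9 were those of the cytoskeletal linker EPPK1 (3.60, SE 0.40), SPOCD1 (3.30, SE 0.53), TMEM265 (3.29, SE 0.40) and the interferon-inducible GTPase GBP2 (3.10, SE 0.48). The phospholipase PLA2G4C (3.07, SE 0.34) and GLIPR1 (2.54, SE 0.46) were also among them. TMEM265 overlaps SRCAP (61.6 CPM) and AC106886.5 (91.4 CPM), both on its strand, and GLIPR1 overlaps KRR1 (63.7 CPM), so both counts are uncertain. In all, 18 of 44 lists passed, 12 higher and 6 lower, 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 10 in fry. The replicate block added the TGF-beta targets (adjusted p = 0.07 without and 0.0107 with it) and the liver and gut genes (0.108 and 9.42e-04, median -1.04, with 0 of 18 members called in edgeR and 2 lower at an unadjusted p under 0.05). Of the TGF-beta targets, 3 of 25 members rose (3 adjusted over the list alone), led by the actin-binding protein TAGLN, which rose by 2.28 (SE 0.41). In the interferon list, 4 of 42 members rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.653, median 0.11, mean -0.05), and DDX58 rose by 1.89 (SE 0.20) while OAS3 fell by 0.87 (SE 0.12). In the cholesterol list, 2 of 27 members rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.197), and in the hypoxia and glycolysis list, 2 of 33 members rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.646, median 0.03, mean -0.01). With control P4 left out, adjusted p was 0.0611 for SPOCD1, 0.0624 for GBP2, 0.0896 for GLIPR1 and 0.066 for TAGLN. With control P17 left out, adjusted p was 0.0675 for GBP2 and 0.0557 for GLIPR1. With TP-0903 P17 left out, adjusted p was 0.0514 for GBP2, 0.0867 for GLIPR1 and 0.0835 for TAGLN.

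The third comparison tested whether the inhibitor and the shRNA against its target change genes differently, as the TP-0903 effect minus the AXL shRNA effect. The effect of the drug was lower for 41 of 41 replication, 39 of 40 mitosis, 14 of 42 interferon, 10 of 26 NF-kB, 16 of 27 cholesterol and 14 of 33 glycolysis genes. These lists passed in camera, and no list did when the correlation was estimated (smallest adjusted p = 0.162 with an estimated correlation). MCM5 differed by -4.12 (SE 0.19, adjusted p = 8.51e-04), the interferon gene OAS3 by -3.28 (SE 0.17), MCM3, of the same helicase as MCM5, by -2.95 (SE 0.17), AURKA by -3.66 (SE 0.22) and ORC6 by -4.93 (SE 0.30). In the other direction SEL1L differed by 2.67 (SE 0.17), CASC4 by 3.03 (SE 0.20), the signalling GTPase HRAS by 2.49 (SE 0.18), the chloride transporter CLCN3 by 1.88 (SE 0.14) and the Golgi protein GCC1, which overlaps ARF5, by 2.53 (SE 0.19). Each gene named for this direction holds a site, as does OAS3.

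The interaction test called 3645 genes, the drug effect higher in 1736 and lower in 1909, and 2374 differed by more than 2-fold. With the replicate block it called 6530, 3282 higher and 3248 lower. Limma on log2 TPM gave 2207 higher and 1266 lower (63.5% against 47.6% higher) and shifted the median gene by 0.19. Effective lengths gave 49.0%. The count was 2375 without control shRNA P15, 1855 without control P17, 1948 without TP-0903 P17 and 2070 without TP-0903 P4.

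List values follow. In the G1/S genes, 41 of 41 members were lower (41 adjusted over the list alone; median -2.86, adjusted p = 2.95e-30, and adjusted p = 0.635 with an estimated correlation). In the G2/M genes, 39 of 40 members were lower (39 adjusted over the list alone; median -3.10, adjusted p = 8.19e-27, and adjusted p = 0.649 with an estimated correlation), and in the DNA repair genes, 1 of 30 members were higher and 22 lower (1 and 24 adjusted over the list alone; median -2.0, adjusted p = 1.22e-11, and adjusted p = 0.649 with an estimated correlation). The control libraries, from which the drug effect was taken, stood above the 6 others in these lists. In the interferon genes, 14 of 42 members were lower (19 adjusted over the list alone; median -1.62, adjusted p = 6.00e-06, and adjusted p = 0.649 with an estimated correlation), and in the NF-kB genes, 10 of 26 members were lower (12 adjusted over the list alone; median -1.74, adjusted p = 6.37e-05, and adjusted p = 0.649 with an estimated correlation). In the cholesterol genes, 2 of 27 members were higher and 16 lower (3 and 20 adjusted over the list alone; median -1.01, adjusted p = 1.16e-05, and adjusted p = 0.649 with an estimated correlation), and in the fatty acid genes, 7 of 14 members were lower (9 adjusted over the list alone; median -0.97, adjusted p = 1.51e-04, and adjusted p = 0.649 with an estimated correlation). Control shRNA stood below control in the cholesterol and fatty acid genes (medians -0.91 and -0.65). AXL shRNA minus TP-0903 gave medians of -0.0078 (4 of 27 higher and 4 lower) and 0.29 (1 of 14 and 0). Among heat shock genes, 10 of 19 members were lower (12 adjusted over the list alone; median -1.01, adjusted p = 2.23e-05, and adjusted p = 0.649 with an estimated correlation). Among hypoxia and glycolysis genes, 1 of 33 members were higher and 14 lower (1 and 15 adjusted over the list alone; median -0.83, adjusted p = 5.45e-05, and adjusted p = 0.162 with an estimated correlation). Among MYC targets, 1 of 33 members were higher and 13 lower (1 and 14 adjusted over the list alone; median -0.75, adjusted p = 2.32e-05, and adjusted p = 0.649 with an estimated correlation). Among ribosomal protein genes, 3 of 75 members were higher and 17 lower (3 and 19 adjusted over the list alone; median -0.39, adjusted p = 2.32e-05, and adjusted p = 0.699 with an estimated correlation). Among stem cell markers, 5 of 17 members were lower (5 adjusted over the list alone; median -0.39, adjusted p = 0.0343, and adjusted p = 0.649 with an estimated correlation). The drug effect lay higher in the lists that follow. In the endoplasmic reticulum chaperones, 10 of 25 members were higher (12 adjusted over the list alone; median 0.60, adjusted p = 2.23e-05, and adjusted p = 0.162 with an estimated correlation). In the ATF4 targets, 6 of 37 members were higher and 1 lower (6 and 1 adjusted over the list alone; median 0.67, adjusted p = 5.60e-04, and adjusted p = 0.649 with an estimated correlation). Control shRNA stood above control in these (0.65), and AXL shRNA minus TP-0903 gave -0.045 (5 of 37 higher and 6 lower). In the lysosome genes, 8 of 36 members were higher and 3 lower (9 and 3 adjusted over the list alone; median 0.28, adjusted p = 0.0176, and adjusted p = 0.649 with an estimated correlation). On TPM the medians were -2.23 for the G1/S list, -2.66 for the G2/M list, -1.42 for the DNA repair list, -0.69 for the interferon list, -1.07 for the NF-kB list, -0.72 for the cholesterol list, -0.74 for the fatty acid list, -0.80 for the heat shock list, -0.54 for the glycolysis list, -0.54 for the MYC targets, -0.16 for the ribosomal protein genes, -0.20 for the stem cell markers, 0.79 for the chaperones, 0.97 for the ATF4 targets and 0.42 for the lysosome genes. In all, 16 of 44 lists passed, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 8 in fry. The replicate block added the STAT3 targets (adjusted p = 0.0522 without and 0.0463 with it), the mesenchymal genes (0.0583 and 0.013) and the fibroblast markers (0.0915 and 0.0191). It also added the nuclear-retained RNAs (0.116 and 0.0323) and the epithelial junction and keratin genes (0.117 and 0.0191). Without AXL shRNA P15, adjusted p was 0.128 for the stem cell list. Without control shRNA P3, adjusted p was 0.069 for the stem cell list. Without control P4, adjusted p was 0.0523 for the stem cell list. Without TP-0903 P4, adjusted p was 0.0546 for the stem cell list. Without control shRNA P15, adjusted p was 0.0675 for the lysosome list.

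Some of the change was common to both treatments, which were measured against separate controls. Across the 17676 genes the log2 fold changes correlated at r = 0.20 (Spearman's rho 0.23). Genes are not independent replicates, and r over the 4 combinations of single cultures ran from 0.164 to 0.230. It was 0.102 without TP-0903 P17. Both treatments raised 419 genes and lowered 344, where independent lists would share 160.4 and 213, while 195 genes rose with AXL shRNA and fell with TP-0903 (208 if independent) and 71 did the reverse (164 if independent). The values if independent apply to these calls only. The shared rises and falls were 1129 and 944 with the replicate block, where more genes were called, and 241 and 383 on TPM. Leaving out any single library gave fewer of both, with fewer genes called for each treatment. BTG2 rose with both (by 2.33 with AXL shRNA and 1.94 with TP-0903), and PHGDH and SLC6A9 fell with both.

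**Figure D3:**
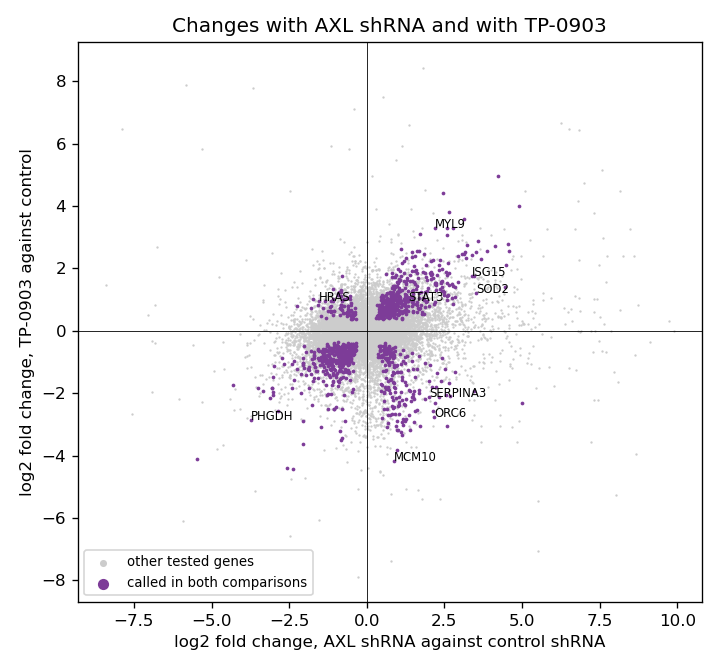
Log2 fold change with AXL shRNA (horizontal axis) against that with TP-0903 (vertical axis), with 1 point for each of the 17676 tested genes and genes called in both comparisons in colour. Of 1029 genes called in both, 763 (74.2%) changed in the same direction.

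The last comparison set control shRNA against control and describes the reference cultures, since the vector, the culture and the P number cannot be separated. Replication and mitosis genes were lower in control shRNA. In the G2/M list, 39 of 40 members were lower (39 adjusted over the list alone; median -3.14, adjusted p = 2.22e-44, and adjusted p = 0.347 with an estimated correlation). In the G1/S list, 41 of 41 members were lower (41 adjusted over the list alone; median -2.23, adjusted p = 9.38e-42, and adjusted p = 0.347 with an estimated correlation), and in the DNA repair list, 23 of 30 (24 adjusted over the list alone; median -1.70, adjusted p = 2.03e-21, and adjusted p = 0.347 with an estimated correlation). Of the cholesterol genes, 18 of 27 were lower (20 adjusted over the list alone; median -0.91, adjusted p = 2.75e-13, and adjusted p = 0.347 with an estimated correlation). Of the ATF4 targets, 6 of 37 were higher (7 adjusted over the list alone; median 0.65, adjusted p = 7.71e-08, and adjusted p = 0.496 with an estimated correlation). AXL stood at -0.51 (SE 0.41, adjusted p = 0.465) and at 0.10 without control P17, and PROS1 at 1.16 (SE 0.50, adjusted p = 0.183). In edgeR's test 1618 genes differed, 541 higher and 1077 lower. The count was 441 without control shRNA P15, 591 without control shRNA P3, 343 without control P17, 897 without TP-0903 P17, 1010 without control P4 and 889 without TP-0903 P4. DESeq2 called 2620, 1153 higher and 1467 lower (44% higher against 33.4%). Of the lists 20 of 44 passed, 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 14 in fry.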

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

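Of the tests in this part, the comparisons of TP-0903 with control shRNA and of AXL shRNA with control were chosen only after the result was seen. The gene lists, the rule for named genes, the interaction test and the main alternatives were fixed before the data were examined. Groups of 2 libraries allow neither a test for outlying libraries nor a count of other splits.

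A set of 23 genes named for either treatment, and 4 gene lists, passed in both treatments with opposite directions. The interaction test passed for each, but opposite calls were the ground of the choice, so it is no independent evidence (adjusted p from 8.51e-04 to 0.00668 for the genes, at most 8.78e-04 with the replicate block). The values are log2 differences, TP-0903 effect minus AXL shRNA effect. For replication and repair genes they were MCM10 (-5.05), ORC6 (-4.93), CDT1 (-4.80), MCM5 (-4.12), XRCC3 (-3.08), MCM3 (-2.95), FANCM (-2.24) and SLBP (-1.71). For mitosis genes they were BUB1B (-3.87), CDK1 (-3.67), AURKA (-3.66), ANLN (-3.58) and CCNB1 (-3.33). Other genes with a lower effect of the drug were HK2 (-4.62), SERPINA3 (-4.13), OAS3 (-3.28), NES (-3.03), EBP (-1.42) and NOP56 (-1.24), which makes 19 of 23. The effect of the drug was higher for HRAS (2.49), PHLDA3 (2.10), NEU1 (1.66) and TIMP2 (1.56). The list medians were -2.86 for G1/S genes, -3.10 for G2/M genes, -0.75 for MYC targets and 0.60 for chaperones. With an estimated correlation these had adjusted p = 0.635, 0.649, 0.649 and 0.162. AXL shRNA minus TP-0903 gave 0.84, -0.067, 0.35 and -0.48 in this order. The chaperone list had 0 members past the threshold with TP-0903, and its adjusted p there was 0.0548 with the block. Some calls in a single treatment were lost without a library. Those with AXL shRNA come first. Without control shRNA P3, adjusted p was 0.0513 for ANLN. Without control shRNA P15, adjusted p was 0.0698 for the G2/M list and 0.386 for the MYC target list. Without AXL shRNA P3, adjusted p was 0.0923 for the G2/M list. The calls with TP-0903 follow. With TP-0903 P17 left out, adjusted p was 0.0833 for TIMP2, 0.0835 for NOP56, 0.0949 for NES, 0.172 for EBP, 0.0844 for HK2, 0.101 for NEU1 and 0.0715 for the chaperone list. With control P4 left out, adjusted p was 0.0578 for TIMP2, 0.0934 for NES, 0.0598 for EBP and 0.052 for HK2. With control P17 left out, adjusted p was 0.0715 for NOP56, 0.111 for NES, 0.2 for EBP, 0.0838 for NEU1 and 0.0712 for the chaperone list. With TP-0903 P4 left out, adjusted p was 0.0522 for NOP56, 0.12 for NES, 0.155 for EBP, 0.0517 for HK2 and 0.0625 for the chaperone list. With AXL shRNA P15 left out, adjusted p was 0.0568 for EBP. With AXL shRNA P3 left out, adjusted p was 0.0579 for EBP.

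Cell cycle genes were lower with TP-0903 than in control, but the control cultures stood above all 6 others in these genes. With an estimated correlation none of these lists passed (adjusted p = 0.338 for each cell cycle list and 0.624 for the integrated stress response list with TP-0903). The median of the G2/M list was 0.43 higher in TP-0903 than in control shRNA, which had no drug. The other lists lay the other way: control shRNA minus TP-0903 gave 0.41 for G1/S genes (13 of 41 higher and 3 lower) and 0.17 for DNA repair genes (6 of 30 higher and 0 lower). With control shRNA in place of control 3320 genes were called for TP-0903. In the integrated stress response list control shRNA lay above control (median 0.65) and TP-0903 below it (-0.72). AXL shRNA, without drug, also lay below control (-0.66). Vector and culture cannot be separated in control shRNA, so a state of the control cultures is not decided there. What lowered the list stays open. For the cell cycle lists a growth state of the control cultures and an effect of the inhibitor cannot be told apart, since no other culture without drug and without a vector was measured. Culture density and duration of treatment were not tested.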

How the results depend on the processing

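Control shRNA in place of control, the counts without genes that hold a 3' UTR site or without cell cycle and repair genes, and control in place of control shRNA were tests chosen only after the data were seen, and all others were fixed before. Where no construction is named, the cause was not tested.

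The count for AXL shRNA was 2522 when tested against a 1.5-fold change, and 3425 among genes whose searched 3' UTR holds no site (fewer genes counted). For TP-0903 it was 3515 with no filter, 3340 with the P number in 2 levels, 548 against a 1.5-fold change and 3320 with control shRNA in place of control. The difference of effects had 1448 against a 1.5-fold change. Control shRNA against control had 3352 with no filter, 2620 in DESeq2 and 2968 with the P number in 2 levels. Every other count of changed genes from a full set of libraries, the block apart, stayed within 1.5 times, including 6507 for AXL shRNA with control in its place, where 4367 of 6627 genes (65.9%) were called in the same direction. Leaving out a library gave 4408 to 6105 genes for AXL shRNA, 489 to 1727 for TP-0903, 1855 to 2670 for the difference and 343 to 1277 for control shRNA against control. These fits ignore the P number pairs, take a lone library to vary like the other groups, and have fewer degrees of freedom.

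With the replicate block TP-0903 had 4647 genes, or 5376 from its own 4 libraries, and the difference had 6530. AXL passed with the block at -0.89 for its shRNA and 0.46 for TP-0903, and at -0.88 and 0.48 from the 4 libraries alone with the block. The block also changed the calls of MERTK and PROS1 for the shRNA, of TYRO3, GAS6 and SMAD2 for the drug, and of lists: fibroblast markers for the shRNA, TGF-beta targets, liver and gut genes and chaperones for the drug, and STAT3 targets, mesenchymal genes, fibroblast markers, nuclear-retained RNAs and keratin genes for the difference. It changed no other call of a list or a named gene, and with it AXL shRNA had 9138 genes, within 1.5 times of 6627. For control shRNA against control, which shares no P number, no paired analysis was possible, and only the number in 2 levels could enter the fit.

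For its shRNA AXL also passed with no filter (-0.95), in DESeq2 (-0.91) and in its own 4 libraries (-0.92), and without single libraries it lay between -1.25 and -0.53. For TP-0903 it lay between -0.064 (without TP-0903 P17, a reversal) and 1.06. Other reversals were of genes that did not pass, given with their range over left-out libraries. For AXL shRNA they were TYRO3 without control shRNA P3 (-0.56 to 0.032) and GAS6 on TPM (-0.11) and without control shRNA P15 (-0.029 to 0.16). For TP-0903 they were MERTK on TPM (0.10), with effective lengths (0.23), and without TP-0903 P17 or control P4 (-0.97 to 0.81), and PROS1 without TP-0903 P17 or control P4 (-0.97 to 0.65). For control shRNA against control they were AXL without control P17 (-0.94 to 0.10), MERTK without control shRNA P3 or control P17 (-0.93 to 1.04), STAT3 without control shRNA P3 (-0.31 to 0.027) and SMAD2 without control shRNA P15 (-0.0077 to 0.20).

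Of list tests, 0 passed in any contrast with an estimated correlation in camera (at an unadjusted p under 0.05, 2 for AXL shRNA, 5 for TP-0903, 3 for the difference and 4 for control shRNA against control). Fry passed 10 for TP-0903 and 8 for the difference. Over the 24 orders of the groups fry passed 22 to 23, 10 to 13, 8 to 13 and 11 to 17, and the smallest adjusted p with an estimated correlation was 0.108. Without single libraries camera passed 16 to 18 lists for AXL shRNA, 13 to 22 for TP-0903, 15 to 22 for the difference and 17 to 24 for control shRNA against control. The correlation of both effects ran from 0.102 to 0.222 without single libraries.

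Over all settings named genes gave, for AXL shRNA (173 results), 3515 values on the same side of the threshold, 103 that no longer passed and 11 that newly did. For TP-0903 (114 results) these were 2034, 346 and 8, for control shRNA against control (10 results) 161, 0 and 4, and for the difference (10 results) all 190 stayed. Of list calls (72), 777 stayed and 139 were lost. In simulated data with 200 changed genes, 25.9% of 2-fold changes were recovered for AXL shRNA and 3.98% for the difference. With as many changed genes as were called here, recovery was not tested.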

Other observations

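Of the tests in this part, the comparison of low with high P numbers, the 3' UTR search and all tests of explanations were chosen only after the data were seen. Predictions for the 8-base class in each culture and for the share of falls with a site were written before those tests. They concern a site found in these same libraries, so they are not independent of the search. Lists not yet described also held changed genes with AXL shRNA, with no passing direction. In the Notch pathway, 4 of 16 members rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.236), and the ligand DLL4 rose by 3.32 (SE 0.40) while HEYL, a target of the pathway, fell by 1.66 (SE 0.21). Of the Wnt targets, 4 of 14 members rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.546), with a rise of the stem cell receptor LGR5 by 7.21 (SE 1.05). Of the ERK output genes, 4 of 18 members rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.511): cyclin D1, CCND1, rose by 1.49 (SE 0.16) and the pathway inhibitor SPRED2 fell by 0.83 (SE 0.11). Of the FOXO targets, 6 of 18 members rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.209): SESN1 rose by 2.06 (SE 0.20) and the insulin receptor substrate IRS2 fell by 2.32 (SE 0.41). Among STAT3 targets, 6 of 21 members rose (6 adjusted over the list alone; camera adjusted p = 0.129): the feedback inhibitor SOCS1 rose by 2.96 (SE 0.40) and the adhesion molecule ICAM1 rose by 3.29 (SE 0.51). In the small RNA processing list, 3 of 12 members rose (3 adjusted over the list alone; camera adjusted p = 0.0948): TNRC6A, a partner of Argonaute, rose by 1.57 (SE 0.14) and the nuclease DICER1 rose by 0.43 (SE 0.12). Of the histone genes, 4 of 11 members rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.147): HIST1H1C rose by 2.36 (SE 0.27) and HIST1H2AC fell by 1.34 (SE 0.15). HEYL, SPRED2, HIST1H2AC and DICER1 hold a site, and DLL4, LGR5, SOCS1 and HIST1H1C were not searched. With control shRNA P15 left out, adjusted p was 0.115 for DICER1. With AXL shRNA P15 left out, adjusted p was 0.0999 for DICER1. With control shRNA P3 left out, adjusted p was 0.0664 for DICER1. With AXL shRNA P3 left out, adjusted p was 0.0695 for DICER1.

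Libraries also differed by P number. With the group in the edgeR fit, 473 of 17676 genes were higher and 396 lower in P3 and P4 than in P15 and P17. The smallest p had the matrix proteins SVEP1 (-3.0, 35.6 to 73 CPM in P15 and P17 and 4.87 to 9.73 CPM in P3 and P4) and NPNT (-4.10, 13.5 to 33.1 CPM in P15 and P17 and 0.615 to 1.99 CPM in P3 and P4). In camera at the preset correlation of 0.01 the interferon list (median -0.47, 7 of 42 members lower, adjusted p = 4.00e-07) and the MHC class I list (-0.45, 7 of 19 lower, 3.80e-07) leaned lower in P3 and P4, and the NRF2 targets (0.26, 4 of 32 higher, 1.44e-07) and the ATF4 targets (0.27, 4 of 37 higher, 4.00e-07) leaned higher. No list passed when the correlation was estimated: adjusted p = 0.712 with an estimated correlation for the interferon list and 0.507 for each of the 3 others.

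Genes that fell with AXL shRNA held a short sequence more often than others in the 3' UTR: of 15523 7-base sequences, GAAGGAA and TGAAGGA, the overlapping parts of TGAAGGAA, had the lowest z (-14.9 and -13.9, where the lowest over 100 permutations of the genes was -4.75). AXL holds TGAAGGAA at 41242883 to 41242890 (exon 11) and at 41252405 to 41252412 (exon 15), both in the coding sequence. The hairpin guide may thus act on other transcripts through its seed. The 745 genes with the 8-base sequence shifted by -0.52 in P15 and -0.48 in P3, from which it was chosen. TGAAGGA and GAAGGAA gave -0.22 and -0.25 alone and -0.43 with both apart, so a joined site is hardly tested. Against 3' UTR length and base composition stand genes not used to choose the site: GAAGGAA ranked first on the odd-numbered chromosomes and on the others, and adjusted for both its z in the set not used was -10.7 and -10.5 (-11.5 and -10.3 unadjusted, at lowest -3.29 for other sequences of the same bases). Sites of 7 bases in the 3' UTR are not the whole cause of the falls (39.2% of the genes called lower hold one, 27.7% of all searched genes), but with 6-base sites and 8-base sites in the coding sequence (shifts -0.10 and -0.21) counted it is 58.1% against 45.3%, and this stays open, as does loss of AXL signalling, since the inhibitor (z = -0.90, shift of the 8-base class -0.03) need not remove the protein, and the guide's sequence and small RNAs of the cell with the same seed were not tested.

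Interferon and NF-kB genes were higher with AXL shRNA (median 1.97 over the 68 genes of both lists). With an estimated correlation each list had adjusted p = 0.595, and on TPM the medians were 0.83 for the interferon and 1.65 for the NF-kB list. What a hairpin vector as such adds is not decided, since control shRNA against control cannot separate vector, culture and P number. There the same genes lay 0.35 above control (interferon list 0.49, NF-kB list 0.03). The AXL shRNA cultures lay at 2.24 and 1.71 (interferon) and 2.09 and 2.69 (NF-kB). Blood cells are argued against: PTPRC, LYZ and CD3E reached at most 0.483 CPM in the AXL shRNA libraries. However, CD79A and HBA1 rose and CD68 lay at 14.4 and 12.5 CPM (20.8 and 12.4 CPM with control shRNA). The endothelial gene CDH5 lay at 9.57 (P15) and 2.98 CPM (P3) against 2.55 and 0.209 CPM with control shRNA. Loss of AXL signalling may contribute and stays open, with a median of 0.22 under TP-0903, as does a response to this particular hairpin, for which no other hairpin was measured.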
